A study of Caenorhabditis elegans with 2 samples.

How the data were processed

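The series holds transcription factor ChIP-seq of whole C. elegans L4 larvae in 2 biological replicates of 1 group, as GEO's labels number them. The values used were 8 peak lists: on each of the 2 genome builds ce10 and ce11, a list for each replicate, a list called on both replicates together and a list of peaks that passed the authors' IDR comparison. Per the deposited file descriptions, each replicate's list was called on that replicate's alignments against a control, the pooled list on both replicates' alignments, and the IDR list was derived from the pooled list and both replicates' lists. The deposited signal value of each peak, in column 7, is the caller's own. Its scale is not given in the sources used here and differs between pooled and single-replicate lists. The deposited −log10 q value of each peak, in column 9, ran from 3.07 to 3.80 in the IDR list and was used to describe that list only. Column 8 held a lone constant, and 2 numeric columns were not used. The peak caller, the aligner, their versions and the IDR threshold are not given in the sources used here.

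The lists were checked before use. Each of the 4293 IDR lines stood unchanged in the pooled list, and exactly 4293 pooled peaks had a signal at or above the lowest IDR signal, so the IDR list is the upper end of the pooled list by signal. No line was identical between the replicates' lists. No 2 lines of a list shared a summit base, and no line lay outside the 6 nuclear chromosomes.

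Positions were compared on ce11 only, with the same assembly's sequence from RefSeq and gene positions from Ensembl release 115. Gene symbols came from the RefSeq annotation by WormBase identifier for 19965 of the 19973 protein-coding genes. Coordinates are 1-based. A gene was called bound where an IDR summit lay from 1000 bp upstream to 200 bp downstream of its annotated start. The ce10 lists entered only counts and comparisons among themselves, with chromosome lengths taken as the last pooled peak's end. Features were assigned in the order promoter window, coding exon, 5' UTR, 3' UTR, intron and intergenic.

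Replicates were compared by the share of replicate 1's strongest peaks overlapping replicate 2's by at least 1 bp, with as many peaks from each as the IDR list holds, against 1000 shuffles within chromosomes by bedtools 2.31.1. Spearman's rho was taken across IDR peaks, with 1000 bootstrap draws of peaks, and carries no test across samples. The promoter share was tested against 1000 random placements. X against autosomes was tested with an exact binomial test on length, and so were arms against centres, after each autosome was divided into 3 equal segments. For CACGTG, occurrences in the 200 bp around each summit were tested against both 200 bp windows centred 400 bp away with an exact binomial test, and its ratio was ranked among all 6-mers with reverse complements joined. Occurrences in overlapping windows were counted in each. The 36 gene lists were tested with Fisher's exact test and Benjamini-Hochberg adjustment at 0.05. A gene belonged to a list if its RefSeq or Ensembl symbol did; this was decided after a first look at the data, when the symbols of some ribosomal protein genes were found to differ, and RefSeq symbols alone gave the same 19 lists past the threshold. For the peaks around each gene named in the labels, the gene body with 20 kb to either side was used. The block around mdl-1 is the run of IDR peaks with gaps of at most 10000 bp that spans the gene. Intervals are exact (Clopper-Pearson) at 95%. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and random seed 1.

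The groups, main tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. Exceptions were the symbol matching and the alternatives said to be chosen later. The tests by signal quartile, of genes bound by chromosome region and of tRNA, snoRNA and other gene types against coding genes were not in that plan. The rule took protein-coding genes with the promoter window over one of the 20 strongest IDR peaks overlapped in both replicates' lists, and up to 4 of the strongest bound members of each list past the threshold and of the Myc/Mondo/Max, longevity and insulin/IGF-1 lists in any case. It also took mdl-1, ZK337.2 and unc-119. Other genes named are said to be chosen after their values were seen. Alternatives covered the genome build, merging, signal threshold, window, summit or midpoint, gene assignment, list background, overlap required, flanks, motif window and control, and each replicate's strongest 4293 peaks alone.

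The tests were tried on simulated data with known answers. With bound genes drawn at random among 19973, 4.0% of 100 draws gave any list past the threshold, and with 8 lists of at least 30 genes raised from 10% to 40% bound, 97.6% of the raised lists were recovered. These draws treated genes as independent, so genes that share a peak and bound shares that vary by region were not simulated. Recovery of lists with fewer than 30 genes was not tried. With 4293 simulated peaks, an X rate raised 1.5 times was recovered as 1.51, and 30% of peaks put at gene starts raised the promoter share by 24.2 points where 23.5 were due. CACGTG had a ratio of 0.946 with none planted and ranked 1 once planted, and 60.0% copied peaks gave 61.3% shared. The depth of the libraries is unknown, since peak lists hold no read counts, so no interval covers counting error in reads. The control libraries and signal tracks were not used here.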

Results

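Chromatin sites of a GFP-tagged transcription factor were mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole Caenorhabditis elegans at the L4 stage, the last larval stage before adulthood. The 2 libraries were biological replicates of 1 group, made from a strain with an unc-119 mutant background and an integrated transgene. Per the labels, both sexes were pooled and the library fragments had a size range of 150 to 350 bp. The labels name different tagged proteins: a free-text description gives eGFP fused to ZK337.2, whereas the strain and antibody fields give mdl-1. MDL-1 is a basic helix-loop-helix leucine zipper protein of the Mad type, in the network of Myc, Mondo and Max proteins. ZK337.2 carries the name klu-1 in the RefSeq annotation. With a lone group, the comparisons were between the replicates, between parts of the genome and between groups of genes. Peak lists carry no read counts, so the depth of each library is unknown and the intervals below cover sampling of peaks or genes only.

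The tagged factor occupied sites that recurred between the replicates. The authors' list of peaks that passed their irreproducible discovery rate (IDR) comparison held 4293 peaks, with signal values from 45.6 to 1411 and a median of 75.0. The list called on both replicates together held 27577 peaks, and the lists of replicate 1 and replicate 2 held 29572 and 28282. Of replicate 1's strongest 4293 peaks, 76.9% shared at least 1 bp with replicate 2's strongest 4293, against a mean of 3.32% and a highest value of 4.22% after shuffling replicate 2's peaks within their chromosomes. The permutation test was one-sided and gave p = 0.001, the smallest value 1000 shuffles can give. Across the 4279 IDR peaks with an overlapping peak in both lists, Spearman's rho between the replicates' signal values was 0.715 (bootstrap 95% interval over peaks 0.697 to 0.734). The log2 ratio of replicate 1 to replicate 2 had a median of 0.10 and a standard deviation of 0.55 across these peaks, which are not independent replicates. A peak's replicate value is that of the strongest overlapping peak, so a weak peak beside a strong neighbour can carry the neighbour's value.

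**Figure D1:**
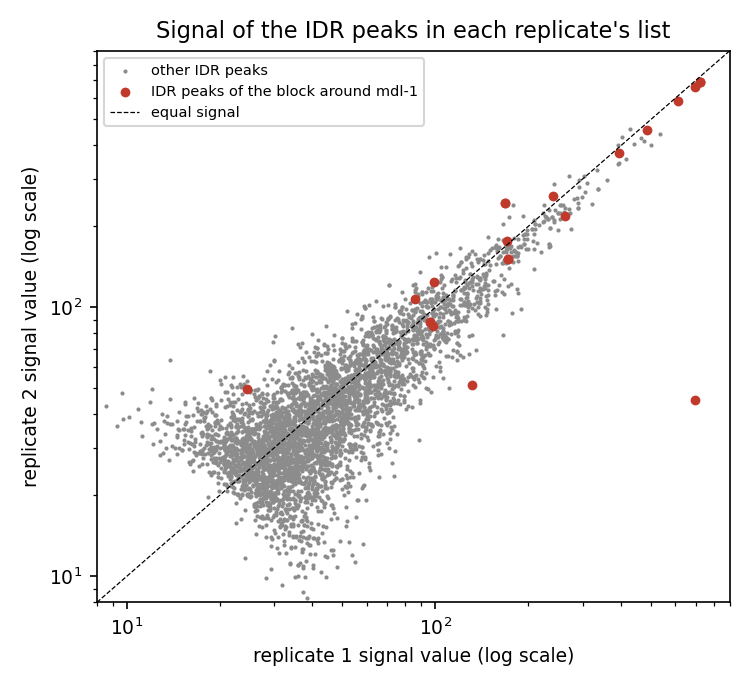
Signal value of each IDR peak in replicate 1's list (x axis, log scale) and replicate 2's list (y axis, log scale), with grey points for the genome at large and red points for the 22 peaks of the block around mdl-1. Points lie along the line of equal signal with a Spearman's rho of 0.715, and the block holds the highest values; the red point far below the line takes its replicate 1 value from a stronger neighbouring peak.

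The strongest peaks in the genome lay in a block around mdl-1. A block of 22 IDR peaks at X:6728925-6750701 (ce11, 21777 bp) spanned mdl-1 (WBGene00003163, X:6742351-6743899, plus strand) and overlapped K11G12.6, R03E9.2 and abts-4, the last of which encodes an anion transporter family member. Its peaks had a median signal of 269, against 74.8 for the other IDR peaks, and 6 of the 20 strongest peaks of the genome lay in it. The mdl-1 promoter peak (X:6741911-6742534, summit 83 bp upstream of the annotated start) had a signal of 1353, with 696 in replicate 1 and 659.9 in replicate 2, and ranked 2 among all IDR peaks. The strongest peak of all, at X:6750057-6750701 in an intron of abts-4, had a signal of 1411. The other gene named in the labels looked ordinary: klu-1 (WBGene00013970, I:14975419-14980596, plus strand) had no IDR peak in its promoter window and 1 within 20 kb, with a signal of 92.4 and rank 1557. unc-119 (WBGene00006843, III:10902641-10908935), the gene mutated in the strain, had 2 within 20 kb and none in its promoter window.

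Counts of peaks within 20 kb of each gene body were set against the same count for all 19973 protein-coding genes, as a description with no test. Around mdl-1, replicate 1's list held 43 peaks and replicate 2's held 35, where the median gene had 11 in each. These counts were at least as high as those of 99.975% and 99.8% of genes. Around klu-1 the lists held 14 and 11 peaks, at least as many as for 67.4% and 53.4% of genes. Outside the block, the most IDR peaks in any window of equal length was 14.

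**Figure D2:**
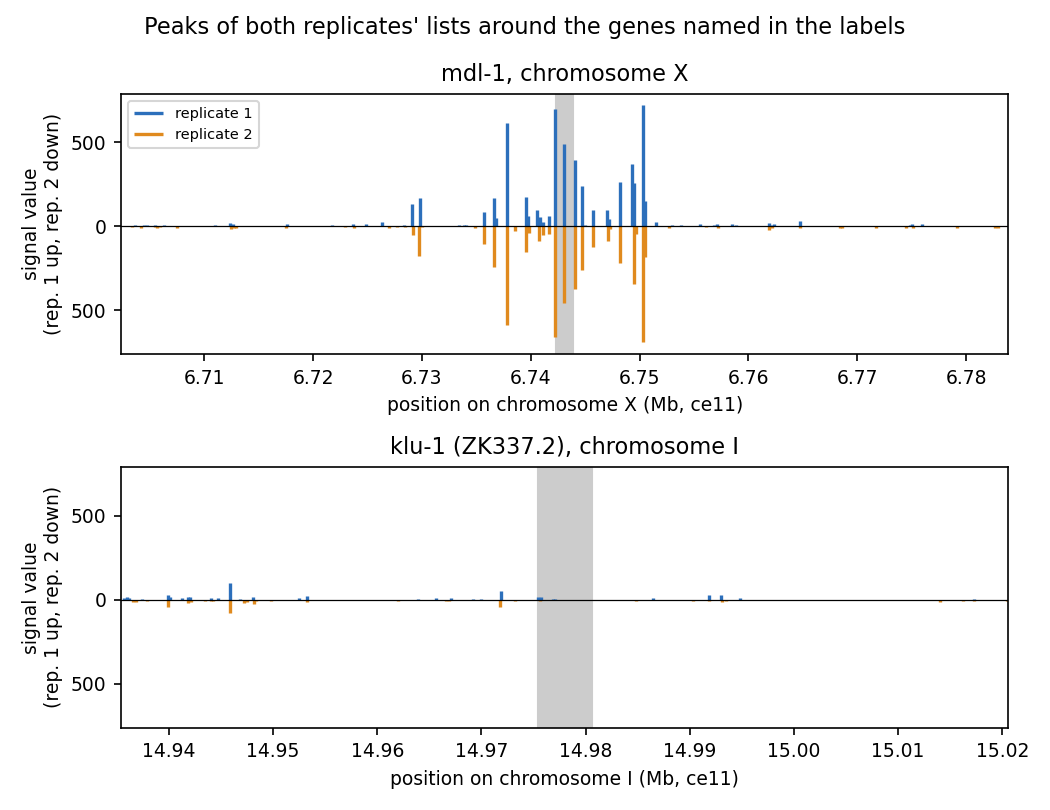
Peaks of replicate 1's list (blue, upward) and replicate 2's list (orange, downward) by position in Mb (ce11) within 40 kb of mdl-1 on X (top) and klu-1 on I (bottom), with bar length giving the signal value and grey marking the gene body. In the block around mdl-1 the highest peak, in an intron of abts-4, reaches 718.8 in replicate 1 and 690.03 in replicate 2. The highest peak drawn around klu-1 reaches 100.3 in replicate 1 and 77.5 in replicate 2, and none within 20 kb of klu-1 exceeds 51.6.

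Binding favoured gene starts. A summit lay from 1000 bp upstream to 200 bp downstream of a protein-coding gene start for 1844 of the 4293 IDR peaks (43.0%), and 29.8% of summits were intergenic beyond these windows, 24.3% intronic and 0.978% in coding exons. Coding exons outside the windows make up 20.04% of the genome and introns 30.5%. In all, 2185 protein-coding genes (10.9%) had a summit in their window, at a median distance of 252 bp, and 93.8% of these summits were upstream of the start. The window reaches further upstream than downstream, which by itself places most summits upstream. Most of the 20 strongest peaks overlapped in both replicates lay outside promoter windows, in introns or between genes. Among these 20, the promoter-bound genes were mdl-1, the divergent pair K01G5.10 and tasp-1 (a threonine aspartase family gene), epn-1 (epsin, an endocytic adaptor), ppm-2 (a protein phosphatase) and mans-3 (an alpha-mannosidase family gene). The peak between K01G5.10 and tasp-1 (III:10759052-10759508) had a signal of 897, 499 in replicate 1 and 400.2 in replicate 2, with its summit 36 bp upstream of tasp-1. The signals at epn-1 (X:14818707-14819225), ppm-2 (III:4649213-4649806) and mans-3 (X:5165031-5165386) were 828, 786 and 653.

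Peaks placed at random within their chromosomes fell in the promoter windows in 21.1% of cases on average (range of 1000 shuffles 19.1 to 23.5%; two-sided permutation p = 0.001998, the smallest 1000 shuffles can give). The share did not change detectably with binding strength, at 43.3% in the lowest signal quartile and 43.7% in the highest (Fisher's exact test, two-sided, p = 0.86). Shuffled positions were not limited to regions to which reads can be aligned.

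The E-box CACGTG, the site bound by Myc, Max and Mad family dimers, was enriched around the summits but lay at a minority of them. It lay within 100 bp of the summit in 791 of the 4293 IDR peaks (18.4%, exact 95% interval 17.3 to 19.6%) and in 3.27% of flanking windows. GAGAGA lay within 100 bp of more summits, 1885 of the 4293. The share with CACGTG rose with binding strength, from 12.5% of the weakest signal quartile to 17.6% of the next to highest and 30.8% of the strongest (Fisher's exact test of the highest against the lowest quartile, two-sided, p = 2.5e-25). The peaks at mdl-1 and mans-3, a peak in an intron of nhr-19 (II:9603365-9603848, a nuclear receptor gene) and an intronic peak in aak-2 (X:16796827-16797252, the catalytic subunit of AMP-activated kinase) carried it. The peaks at tasp-1, epn-1 and ppm-2 did not. nhr-19 and aak-2 were named after their values were seen.

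The 200 bp around the summits held 843 occurrences, and the pair of 200 bp windows centred 400 bp to either side held 295. Per window this is a ratio of 5.72 (exact 95% interval 4.9997 to 6.55; exact binomial test, two-sided, p = 1.5e-173). The median ratio of all 2080 6-mers was 1.101, and CACGTG ranked 10. The 6-mers above it were the GC-rich GCGCGC (8.35) and CGCGCG (7.07), the GA repeats AGAGAG (7.67) and GAGAGA (7.30), and ACGCAG (6.35), CGTCTC (6.09), AGACGC (6.02), AGAGAC (5.97) and GACGCA (5.95).

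**Figure D3:**
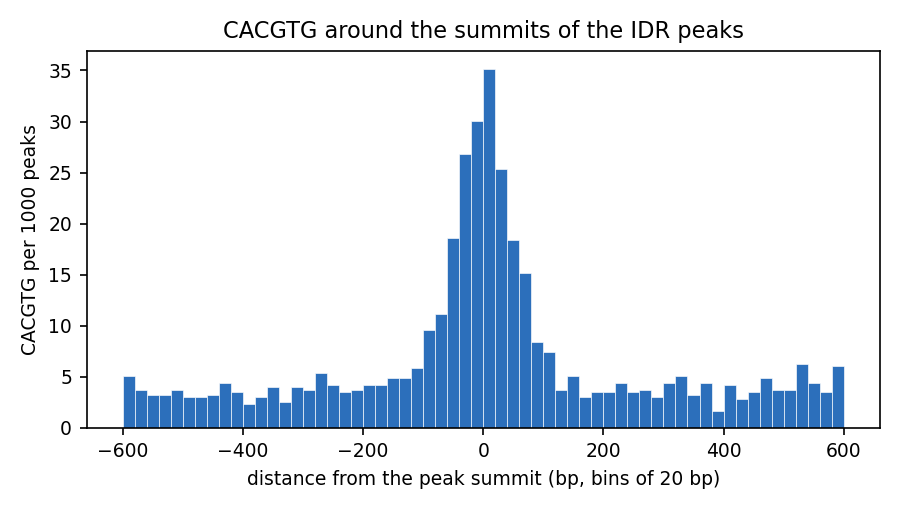
Occurrences of CACGTG per 1000 IDR peaks (y axis) by distance from the summit in bins of 20 bp (x axis). Occurrences pile up within about 100 bp of the summit, where 843 were counted in the 200 bp around the summits, and are flat beyond.

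Promoters of ribosomal protein, translation factor, respiratory chain, proteasome and V-ATPase genes were bound more often than those of other protein-coding genes, of which 10.9% were bound in all. Of the ribosomal proteins, 20 of 31 small-subunit genes (64.5%) and 32 of 49 large-subunit genes (65.3%) were bound, the strongest being rpl-15 (signal 454), rpl-3 (410.5), rpl-14 (339) and rps-12 (334). Bound were also 15 of 40 translation factors (37.5%), led by the initiation factor iff-2 (575) and the elongation factors eef-1A.2 (497) and eef-1A.1 (194). Of the respiratory chain and ATP synthase genes 21 of 51 were bound (41.2%), including the succinate dehydrogenase subunit sdha-1 (286) and the cytochrome oxidase subunits cox-5B (209) and cox-5A (196). The proteasome followed with 12 of 33 (36.4%; rpn-11, 146; rpn-13, 125) and the V-ATPase, the lysosomal proton pump, with 7 of 20 (35.0%; vha-12, 184; vha-13, 103.9). With each peak given to the nearest gene start, 29.0% of small-subunit (odds ratio 2.92), 42.9% of large-subunit (5.38) and 25.5% of respiratory genes (2.45) were bound and still passed, and V-ATPase genes did not (Fisher's exact test, adjusted p = 0.15). The proteasome list did not pass with peaks at or above the median signal (adjusted p = 0.21, the same exact test) or with genes at least 500 bp from the next gene upstream (adjusted p = 0.082).

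The unfolded protein response, chaperone, autophagy, heterochronic and nuclear hormone receptor lists passed as well. The unfolded protein response list had the highest bound share, 9 of 12 genes (75.0%): atf-4 (259.8 in signal), the kinase gene pek-1 (249), the transcription factor gene xbp-1 (220.4) and the ER chaperone gene hsp-3 (169) led it. Among heat shock and chaperone genes, 16 of 63 were bound (25.4%), with dnj-14 (195), hsp-3, the chaperonin gene cct-7 (128) and hsp-1 (127) highest. Autophagy genes were bound in 11 of 24 cases (45.8%), among them the Atg8 homologs lgg-2 (289.6) and lgg-1 (209.8) and atg-9 (279.8). Heterochronic genes, which time larval development, were bound in 8 of 14 cases (57.1%), with nhl-2 (568), lin-66 (208), mab-10 (132) and ain-1 (126) highest. Nuclear hormone receptors were bound in 56 of 269 cases (20.8%), with nhr-32 (465), nhr-68 (343), nhr-135 (318) and nhr-48 (250.03) highest. By Fisher's exact test the chaperone excess was absent with each peak given to the nearest gene start (8 of 63, 12.7% against 12.3% of other genes, adjusted p = 0.99) and did not pass with genes at least 500 bp from the next gene upstream (adjusted p = 0.12). Heterochronic genes did not pass with a window of 500 bp upstream (adjusted p = 0.064, the same exact test).

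Longevity transcription factors were bound in 6 of 14 cases (42.9%): mdl-1, nhr-49 (185), the insulin-pathway effector daf-16 (142) and nhr-80 (70.4) were the strongest. The insulin/IGF-1 list itself had 3 of 10 members bound, akt-2 (176), daf-16 and pptr-1 (58.5), and did not pass the threshold (Fisher's exact test, adjusted p = 0.15). It did pass, by the same exact test, with each peak given to the nearest gene start (5 of 10, adjusted p = 0.011) and without replicate 1 (4 of 10, adjusted p = 0.029). Of the Myc/Mondo/Max network, mdl-1, mxl-3 (66.7) and mml-1 (61.7) were bound and mxl-1 and mxl-2 were not, so that 3 of 5 members were bound. The mdl-1 value belongs to the block that stands apart from the rest of the genome. Fatty acid metabolism genes were bound in 8 of 25 cases (32.0%; acs-2, an acyl-CoA synthetase, 377; nhr-49, 185; the lipase genes atgl-1, 76.2, and lipl-5, 73.7). Bound were also pan-neuronal genes (7 of 22, odds ratio 3.81; tbb-1, 172; rgef-1, 150.2), core cell cycle genes (7 of 26, 3.01; the Rb homolog lin-35, 126; cyclin E cye-1, 95.8) and RNA polymerase II and general factors (13 of 56, 2.47; cdk-7, 279.7; taf-10, 175). The pan-neuronal list did not pass with genes at least 500 bp from the next gene upstream (5 of 20, Fisher's exact test, adjusted p = 0.12) or with only genes that had a peak of the pooled list (7 of 12, adjusted p = 0.14).

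Chemoreceptor genes were bound less often than other genes, and sperm genes were in the main test but not under every alternative. Chemoreceptor genes encode receptors of sensory neurons and were bound in 18 of 1294 cases (1.39%; srh-17, 169), and sperm genes in 1 of 81 (1.23%; spe-46, 82.8; 2 of 81 without replicate 2). By Fisher's exact test the sperm list did not pass with peaks at or above the median signal (adjusted p = 0.19), with genes at least 500 bp from the next gene upstream (0.082) or with only genes that had a peak of the pooled list (1 of 9, 0.61). None of 24 germline, 21 epidermis and 15 pharynx genes was bound, with upper exact 95% limits of 14.2, 16.11 and 21.8%. These 3 lists did not pass the threshold, nor did cuticle collagens (11 of 176, Fisher's exact test, adjusted p = 0.092), histones (5 of 72), homeobox genes (7 of 89), intestine genes (4 of 26), body wall muscle genes (3 of 24) or microRNA genes (43 of 258). Also short of it were bHLH genes (6 of 40), glycolysis (4 of 19), aminoacyl-tRNA synthetases (4 of 31), Wnt (5 of 25), TGF-beta (4 of 16), Notch and EGF/Ras (1 of 21) and oxidative stress genes (1 of 20). Without replicate 1, collagens (6 of 176, adjusted p = 0.0026) and homeobox genes (3 of 89, 0.038) passed as lower and glycolysis as higher (6 of 19, 0.022) by the same exact test, and 2 of 20 oxidative stress genes were bound. Without replicate 2, collagens passed as lower (9 of 176, adjusted p = 0.026, exact test), and 4 of 21 Notch and EGF/Ras, 3 of 25 Wnt and 2 of 20 oxidative stress genes were bound. With each peak given to the nearest gene start, glycolysis (9 of 19, adjusted p = 0.00060) and TGF-beta genes (8 of 16, 0.00080) passed as higher and collagens as lower (11 of 176, 0.023) by the same exact test. With peaks at or above the median signal, collagens passed as lower (0 of 176, adjusted p = 0.00040) and microRNA genes as higher (29 of 258, 0.037) by exact test. Clustered microRNA genes can share a single peak, so the test treats as independent genes that are not.

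Each list was compared with all other protein-coding genes (microRNAs with other non-coding genes) by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 36 lists. Of these, 19 passed an adjusted p of 0.05, 17 with a higher and 2 with a lower bound share. Some lists share bound members, so their calls are not separate. For example, hsp-3 counted in the unfolded protein response and chaperone lists. mdl-1 and mml-1 counted in the longevity and Myc/Mondo/Max lists, and nhr-49 and nhr-80 in the longevity, fatty acid and nuclear hormone receptor lists. The adjusted p was 2.6e-18 for large-subunit ribosomal proteins (odds ratio 15.5), 1.7e-11 for small-subunit ones (14.9), 2.4e-07 for respiratory genes (5.74), 2.6e-06 for the unfolded protein response (24.5), 1.6e-05 for nuclear hormone receptors (2.17), 5.3e-05 for translation factors (4.91) and 7.6e-05 for autophagy (6.92). It was 0.00013 for heterochronic genes, 0.00040 for the proteasome, 0.0032 for chaperones, 0.0065 for longevity factors, 0.0095 for both V-ATPase and fatty acid genes, 0.016 for pan-neuronal genes, 0.017 for general factors, 0.022 for the Myc/Mondo/Max network and 0.036 for the cell cycle. Without replicate 1 the odds ratio was 8.99 for small-subunit ribosomal proteins (16 of 31), 42.1 for the unfolded protein response (10 of 12) and 2.69 for the proteasome (8 of 33), and all still passed. For the lower lists the adjusted p was 4.8e-42 (chemoreceptors, odds ratio 0.107) and 0.0056 (sperm, 0.101). With only genes that had any peak of the pooled list in their window, 11 lists passed, 10 of them among the 19, a background chosen after seeing the data. Only 8 of the 19 lists passed under every alternative: both ribosomal lists, translation factors, autophagy, respiratory genes, the unfolded protein response, nuclear hormone receptors and chemoreceptors. With only genes that had a pooled-list peak, all 8 had weaker odds ratios than in the main test. The ratio fell to 6.91 for large-subunit and 5.16 for small-subunit ribosomal proteins and 11.6 for the unfolded protein response. It fell to 2.75 for translation factors, 4.04 for autophagy, 3.61 for respiratory genes and 1.91 for nuclear hormone receptors. For chemoreceptors it rose to 0.434 (14.6% bound against 28.3%). By the same exact test the cell cycle list lost its call under 7 of 9 alternatives, among them either replicate's strongest peaks alone (adjusted p = 0.081 and 0.093), general factors lost it under 4, and the Myc/Mondo/Max network lost it without the block around mdl-1 (adjusted p = 0.16). Longevity and fatty acid genes did not pass with 500 bp upstream (adjusted p = 0.064 and 0.12, exact test) or with peaks at or above the median signal (0.097 and 0.28). Expression and chromatin accessibility were not measured here, so the lists were not matched for either.

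**Figure D4:**
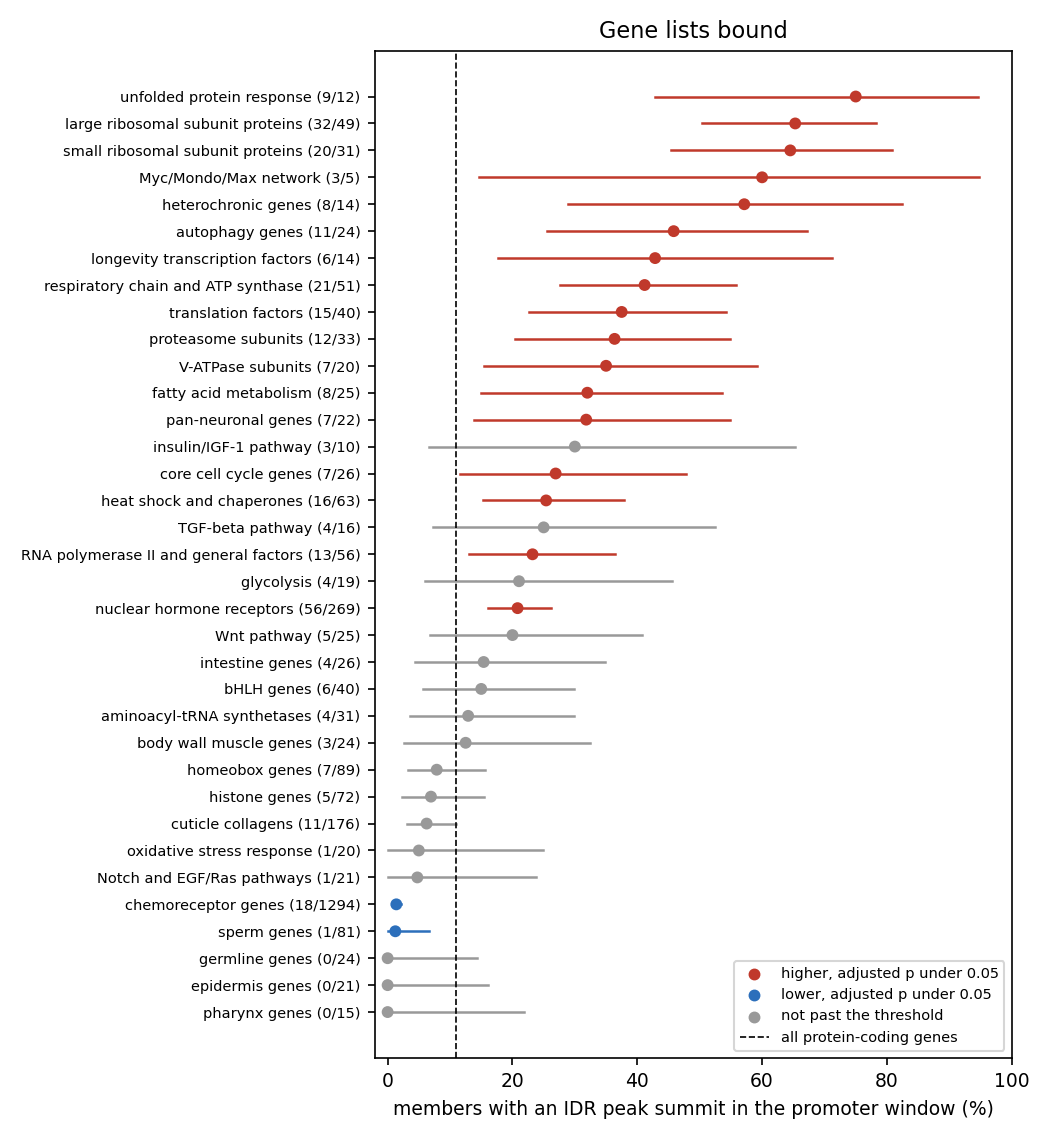
Percent of each list's protein-coding members with an IDR summit in the promoter window (x axis; bound and measured numbers in brackets), with exact 95% intervals as bars and the 10.9% of all protein-coding genes as a dashed line. Red lists passed an adjusted p of 0.05 with a higher share, blue lists with a lower one and grey lists did not pass; the unfolded protein response (75.0%) and the ribosomal proteins lie highest.

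The X chromosome was bound more densely than any autosome, and autosome centres more than arms. X carried 1036 IDR peaks, 58.5 per Mb, whereas the autosomes ranged from 33.8 per Mb on V to 46.3 on III. Of 2731 X-linked protein-coding genes 15.2% were bound, against 10.3% of autosomal ones (Fisher's exact test, two-sided, p = 2.0e-13). On the autosomes, 12.8% of genes in the central segments and 8.69% in the arms were bound (Fisher's exact test, two-sided, p = 7.8e-18). X-linked genes with strong promoter peaks outside the block included epn-1, mans-3, eef-1A.2, nhr-32 and sdha-1.

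Per Mb, the ratio of X to autosomes was 1.48 (exact 95% interval 1.38 to 1.59; exact binomial test, two-sided, p = 2.0e-26). Per protein-coding gene it was 2.01, or 1.77 for promoter-window peaks alone, and for peaks outside promoter windows it was 1.62 per Mb of whole chromosome. That last ratio was not taken over the sequence outside the windows. X has fewer coding genes per Mb than the autosomes, which can raise it. The ratio of arms to centres was 0.587 per Mb (0.548 to 0.629, p = 1.7e-50) and 0.723 per protein-coding gene by the same exact test. Peaks cluster along the genome, so these p-values treat as independent peaks that are not.

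**Figure D5:**
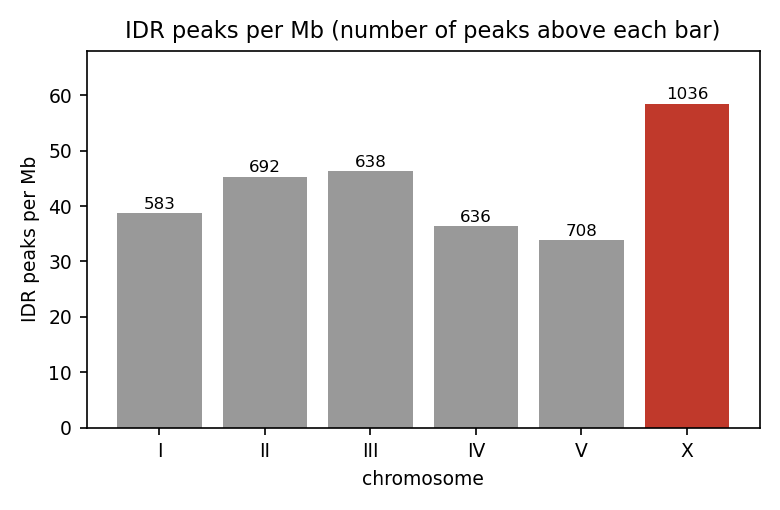
IDR peaks per Mb (bars, from 0) for each nuclear chromosome, with X in red and the number of peaks above each bar. X stands at 58.5 per Mb, above the 33.8 to 46.3 per Mb of the 5 autosomes.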

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

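Of 59 values of the main results under alternatives, 55 kept their call and none reversed. A tested result kept it on the same side of its threshold, a count within 1.5 times, and rho inside its bootstrap interval. Alternatives that left out the block around mdl-1, changed the list background to genes with a pooled-list peak, used RefSeq symbols alone, or varied the tRNA, snoRNA and named-gene counts were chosen after seeing the data. The 4 that moved were these. With only peaks at or above the median signal, the IDR list held 2147 peaks by construction and rho across peaks was 0.742. With a reciprocal overlap of 0.5, rho was 0.629, and the cause was not tested. With only genes that had a peak of the pooled list, 11 gene lists passed in place of 19. The other settings gave 13 to 22 lists. From each replicate's strongest peaks alone, the promoter share was 41.9% in both cases, the X ratio 1.49 to 1.54, the arm ratio 0.576 to 0.577, the CACGTG ratio 5.34 to 5.72, and the lists passing 19 to 22. CACGTG then ranked 9 without replicate 1 and 11 without replicate 2, and it ranked 3 (ratio 8.50) in 100 bp windows and 6 (7.59) with peaks at or above the median signal. Among single lists, 278 of 324 values kept their call, 34 lost it, 12 gained it and none reversed. The 8 lists that passed under all 9 alternatives were both ribosomal lists, translation factors, autophagy, respiratory genes, the unfolded protein response, nuclear hormone receptors and chemoreceptors. Their calls held but their effect sizes did not stay equal, and all 8 odds ratios were weaker with only genes that had a pooled-list peak. By exact test, calls were lost at 500 bp upstream by 6 lists (Myc/Mondo/Max, general factors, cell cycle, fatty acid, heterochronic, longevity; adjusted p = 0.064 to 0.12). With peaks at or above the median signal the first 4 of these, longevity, proteasome and sperm lost theirs (exact test, adjusted p = 0.097 to 0.38). With genes 500 bp or more from the next gene upstream, cell cycle, chaperones, pan-neuronal, proteasome and sperm did (exact test, adjusted p = 0.053 to 0.12), and with the nearest start general factors, V-ATPase, cell cycle and chaperones did (exact test, adjusted p = 0.060 to 0.99). With only genes that had a peak of the pooled list, Myc/Mondo/Max, general factors, V-ATPase, cell cycle, fatty acid, chaperones, longevity, pan-neuronal and sperm lost theirs (exact test, adjusted p = 0.14 to 0.61). Calls were gained with the nearest start by TGF-beta, glycolysis, insulin/IGF-1 and, lower, collagens, by collagens under 4 other settings, by insulin/IGF-1, glycolysis and, lower, homeobox genes without replicate 1, and by microRNAs with peaks at or above the median signal. Without the block around mdl-1 the X ratio was 1.45. Library depth is unknown, so its effect on weak peaks was not assessed.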

Other observations

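Chosen only after the result was seen were the comparisons of CACGTG by gene list, the microRNA loci, the densities of CACGTG and GAGAGA on X, and the tests of distance from coding starts and of identical snoRNA copies. The tests of tRNA, snoRNA and other gene types against coding genes were not planned. For the other explanations weighed here the predictions were written before their values were seen.

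CACGTG within 100 bp of the strongest summit was counted among the bound members of each list: 0 of 20 small-subunit and 1 of 32 large-subunit ribosomal protein genes (rpl-14) had it, and 0 of 15 translation factors. The counts were also 0 of 21 respiratory, 0 of 16 chaperone, 0 of 13 general factor, 0 of 12 proteasome, 0 of 11 collagen and 0 of 8 heterochronic genes, with upper exact 95% limits up to 36.9%, and translation genes were not tested against these lists. It lay at 15 of 56 bound nuclear hormone receptors and 4 of 11 bound autophagy genes. None of the 22 lists with at least 5 bound members differed from the other bound genes after adjustment (Fisher's exact test, lowest adjusted p = 0.34). The ribosomal protein and translation factor lists were joined after their counts were seen: 1 of 67 bound genes (1.49%, 0.0378 to 8.04%) had CACGTG, against 338 of 2118 other bound genes (15.96%), values given with no test since the lists were chosen for their counts. When only the 791 peaks with CACGTG were used to call genes bound, 3 of 35 lists passed an adjusted p of 0.05. By Fisher's exact test, two-sided, these were nuclear hormone receptors (15 of 269, 5.58% against 1.69% of other genes, adjusted p = 0.0014), autophagy genes (4 of 24, 16.7% against 1.72%, adjusted p = 0.0085) and, with a lower share, chemoreceptors (3 of 1294, adjusted p = 1.4e-05). The autophagy genes were atg-9, atg-3, epg-5 and atg-13. The nuclear receptors nhr-32, nhr-68 and nhr-135 had the strongest of the receptor peaks with CACGTG. Fatty acid metabolism (lipl-5, lipl-2 and fasn-1; 3 of 25) had an adjusted p of 0.079.

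Among microRNA loci, the strongest peak in a promoter window (X:13145123-13145618, ce11) lay at the mir-54, mir-55 and mir-56 cluster inside F09A5.3, with a signal of 652, 359 in replicate 1 and 298 in replicate 2, and with CACGTG near its summit. mir-8186.2 (signal 302), mir-5595 (277), mir-52 (269.6) and mir-241 of the let-7 family (208) came next. These were named after their values were seen.

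The labels name 2 tagged genes. If the factor binds E-boxes as MDL-1 is expected to, CACGTG should stand among the top 10 6-mers, and it ranked 10, with 3 in 100 bp windows, 6 among peaks at or above the median signal, 9 without replicate 1 and 11 without replicate 2. If an integrated copy of the tagged gene's region raised its read depth, peaks should crowd around that gene in both replicates: the counts around mdl-1 stood at or above 99.8% of genes, and those around ZK337.2 at or above no more than 67.4%. The values argue against a transgene that raised the peak count around ZK337.2, and go with a tagged mdl-1. Peaks were called against a control, so extra copies also present in that control could go unseen. No binding site of ZK337.2 was tested. Binding of the factor to its own gene may also fill the block, and 5 of its 6 strongest peaks carried CACGTG, so extra copies and true occupancy remain open for the block. Other E-box factors were not excluded by these values.

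X held more peaks per Mb than the autosomes. More CACGTG or GAGAGA sites on X are argued against, at 0.753 and 0.917 times the autosomes' number per Mb of sequence, whereas the other 6-mers enriched at summits were not counted on X. An excess of callable regions on X in general could contribute, since the 23284 pooled peaks outside the IDR list also had a ratio of 1.31 (exact 95% interval 1.27 to 1.35), rising from 1.17 in their weakest signal quartile to 1.44 in the strongest. These peaks continue the IDR list at lower signal and may hold weaker binding. Their ratio therefore cannot tell callable regions from binding. The IDR peaks stood at 1.48 (1.38 to 1.59), with 1.19 (1.06 to 1.33) for those with GAGAGA within 100 bp and 1.73 (1.58 to 1.89) for those without, and 1.39 with CACGTG and 1.503 without. No biological explanation was tested, and what makes regions callable on X was not measured here.

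Starts of tRNA and snoRNA genes were bound more often than coding starts: 165 of 612 tRNA genes (26.96%) and 105 of 346 snoRNA genes (30.3%), against 10.9% of coding genes (Fisher's exact test, two-sided, adjusted p = 1.5e-26 and 8.1e-22). Nearness to coding starts alone is argued against, since 24.8% (21.3 to 28.5%) of those over 1200 bp from every coding start were bound. In that set 26.15% of 390 tRNA genes and 21.99% of 191 snoRNA genes were bound. The snoRNA share there was below the 30.3% of all snoRNA genes, so a part played by nearness remains open for them. The E-box is argued against too, as it lay at 5.67% of peaks at tRNA and snoRNA starts against 19.2% of other peaks. Reads shared among identical copies remain open for tRNA genes: 15% (9.53 to 22.01%) of the 140 without an identical copy were bound, an interval that includes the coding share, against 30.5% of the 472 with copies. For snoRNA genes they are argued against, as 30.6% (25.8 to 35.8%) of the 343 without an identical copy were bound. A general tendency of highly transcribed small RNA genes to be recovered in ChIP could not be tested without control libraries, and no biological explanation was tested.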
